A study of Mus musculus with 60 samples.

How the data were processed

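Genomic DNA from whole embryos and placentas had been extracted with a column kit, cut with MspI, ligated to methylated adaptors, bisulfite converted and amplified by index PCR, per the labels' protocols. The authors used Trim Galore 0.3.3, BSMAP 2.74 and Picard with the mm10 build, per the submitters' processing notes; the role and order of these tools are not given in the sources used here. Each library's deposited file lists CpG positions with a coverage count, the number of reads, per the file headers. The same deposited files give the percent of those reads that were methylated and unmethylated, per the file headers. Forward and reverse strand positions stand on their own lines and were joined here into CpGs. In most libraries 1 position had the same highest coverage, so the count appears to be capped there. PCR reads without molecular identifiers are not independent molecules, and a read counts at each CpG it covers. Counting intervals are therefore too narrow, and they cover counting error only.

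Methylated reads were recovered as coverage times percent divided by 100, rounded to whole reads, and summed for both strands over fixed tiles of 100 bp. Of 2468380 CpGs seen in any library, tiles with at least 2 CpGs numbered 493420. Reads of a tile or region are this sum, so a read counts once for each CpG it covers and fewer sequenced reads lie behind it. Every fit used tiles on the autosomes and X with at least 15 such reads in every library of the fit and a mean level of 5 to 95%. Coordinates are mm10, counted from 1. Levels are percent methylated reads of a tile, and group values are means of libraries with the SD.

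Groups were taken from the labels: 12 groups of 5 libraries, 60 in all. Libraries of a group are called biological replicates in the labels, without saying which share a litter. A chi-square per tile between libraries of a group ranged from 1.99 to 6.40, so no 2 libraries agreed within sampling noise. Replicate numbers recur across groups. They were not treated as pairs, since same-numbered deviations over tiles were correlated between −0.0759 and 0.0502 and the labels do not say what a number marks.

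Tiles were tested with a quasi-binomial logistic model in R 4.3.3, with dispersion from Pearson residuals moderated across tiles by limma 3.58.1 and not allowed under 1, an F test and Benjamini-Hochberg adjustment. A tile was called at an adjusted p under 0.05 and a difference of at least 10 points between group means. The planned tests were 10 two-group comparisons of 5 against 5 (Het minus WT in 6 sets, ART minus NAT in 4), 3 sex comparisons with genotype as covariate, 1 tissue comparison, and 7 interactions. Mean autosomal level, variability, imprinted regions and gene lists were further families. Imprinted regions were adjusted over the regions of each comparison, the others over the 10 comparisons. Single values were compared with two-sided exact permutation tests, or with 100000 draws where groups had 10 or more libraries. Joint models over 60 libraries and 40 placentas, comparisons with the opposite NAT sex label, counts of autosomal tiles alone, the sex chromosome check, the tests of single CpGs within tiles, by permuting genotype within the 6 sets, the tests on replicate numbers, gene lists over the tiles shared by both NAT labels and the 20 against 20 tests of imprinted regions were added after the data were examined. The comparisons, thresholds and gene lists named before them were set before the data were examined.

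Named genes followed a fixed rule. In each comparison called tiles were ranked by absolute difference, keeping 1 tile per gene within the gene or 5 kb of it and passing over unnamed predicted genes. The first 6 higher and 6 lower were named, or 4 each way for sex and tissue and 4 for interactions. Where fewer than 3 tiles were called, the 3 tiles of smallest p with a gene were given, as values. Imprinted regions with data and listed genes with a called end tile were named in addition. In the genotype model added later all named genes with a called tile were given, and in the conception model the genes were chosen after their values were seen, as was the tile on chr5 at 53398601.

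The gene table used (GRCm38.p6, the assembly behind mm10) gives gene spans without strand, start sites or exons. Promoters and the planned 5 kb upstream of a gene could therefore not be taken, and 5 kb on either side was used for naming genes. For the gene lists tiles from 1.5 kb outside to 0.5 kb inside either end of a gene were used instead of promoters, and whether a tile is exonic, intronic or in a UTR is not known here. All members of the 12 gene lists were found by symbol. Imprinted germline regions were taken from mm10 intervals set down from general knowledge and not checked against an annotation, using tiles of intermediate mean level over all 60 libraries.

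The tile test was tested on simulated counts drawn at each comparison's own levels and spread, with 200 changed tiles each. Of tiles changed by 30 points, 74% (ART minus NAT, Het placentas labelled male) to 90% (Het minus WT, female ART embryos) were called, and false calls were 4.29% to 20% of calls over the 10 comparisons. This share depends on the 200 changed tiles and is not that of the real lists. The adjustment aims at a share of at most 0.05, which every comparison but Het minus WT in female ART placentas exceeded. Of unchanged tiles, 5.37% to 6.98% had an unadjusted p under 0.05 by the quasi-binomial test. The test was thus somewhat too liberal in these simulations. In the 6 Het minus WT comparisons the simulations had 9, 11, 3, 14, 6 and 10 false calls, while the real lists held 10, 12, 0, 1, 2 and 2 tiles. No simulation without changed tiles was run. Depth sets the precision: the median coverage per CpG was 10 to 27 reads over libraries. Every tile tested had at least 15 reads in each library of its fit, summed over its CpGs, which can be fewer sequenced reads.

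Alternatives set beforehand were 30 reads, 20 points, a plain binomial model, limma on log2 ratios with an offset of 0.5, no filter on the mean level, tiles of 500 bp, replicate blocks, a deviation of 30 points, pooled reads for the mean level, all tiles or an exact test for imprinted regions, and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables handled with the data.table package (1.17.8).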

Results

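DNA methylation was measured by reduced representation bisulfite sequencing (RRBS), which reads CpG positions near MspI cut sites, in 60 libraries of mouse embryos and placentas at E11.5. The background strain was 129S2/SvPasCrl. Embryos and placentas had been obtained with assisted reproductive technologies (ART), and further placentas came from natural mating, written NAT here. Within each of these 3 sets the labels gave a sex and a genotype, wild type (WT) or heterozygote (Het) for Dnmt1o, the oocyte form of the maintenance methyltransferase Dnmt1. This made 12 groups of 5 libraries named as biological replicates. The labels do not say whether the genotype is that of the conceptus or of its mother. Library depth, as the sum of reads at CpGs, was 57087846 to 114623246 reads in ART embryos, 55825869 to 108984020 in ART placentas and 36537036 to 114724952 in NAT placentas. The deposited values were read coverage counts and percent methylation per CpG, and reads were summed over tiles of 100 bp.

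Reads from the sex chromosomes separated the libraries cleanly, but in the NAT placentas they went against the sex label. Y reads at CpGs, divided by the library's autosomal reads at CpGs and scaled as RPM, averaged 1606 ± 202 (SD, n = 10) in NAT placentas labelled female and 598 ± 117 in those labelled male. ART placentas labelled female had 536 ± 106 and those labelled male 1715 ± 259, and ART embryos had 487 ± 99.2 and 1669 ± 164 (SD, n = 10 each). X reads per 1000 autosomal reads averaged 17.0 and 31.1 in NAT placentas labelled female and male, against 30.9 and 17.4 in ART placentas. The same order held for 1523 X tiles that had a low level in ART libraries labelled male. Their mean level was 2.11% ± 0.359 in NAT placentas labelled female and 11.6% ± 0.697 in those labelled male, with 2.31% ± 0.303 in ART placentas labelled male (SD, n = 10). ART placentas labelled female ranged from 10.5% to 12.1%. Labels were kept as given in every planned comparison, and each NAT group is called by its label below.

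**Figure D1:**
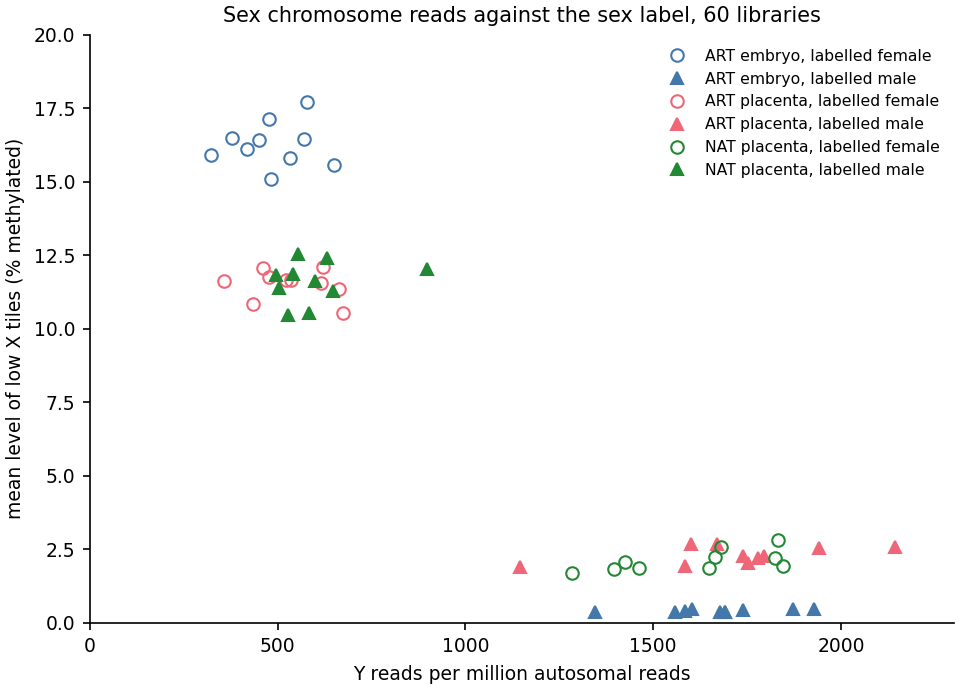
Each point is a library; the horizontal axis gives Y reads (RPM of autosomal reads) and the vertical axis the mean methylation (%) of 1523 X tiles that were low in ART libraries labelled male. NAT placentas labelled female (mean 1606 RPM) lie among ART placentas labelled male, and NAT placentas labelled male (598) lie by ART placentas labelled female.

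Placenta and embryo differed over most of the measured genome. ART placentas had a mean autosomal level of 30.5% ± 0.950 (SD, n = 20) over 153790 tiles and ART embryos 43.0% ± 0.396, while NAT placentas had 31.0% ± 1.07. Of 113576 tiles tested between ART placenta and embryo, 87724 were lower and 9790 higher in placenta. A tile within Bcl11b, a transcription factor of T cell development (chr12 107915601), fell to 18.5% ± 5.02 in placenta from 94.8% ± 1.90 in embryo (SD, n = 20). Tiles within Npepl1 (9.05% against 93.2%) and G3bp2 (7.98% against 88.1%) and beside Zbtb8a (15.5% against 92.3%) fell by similar amounts. Tiles within Cercam rose from 4.25% ± 2.39 in embryo to 69.5% ± 5.27 in placenta, and tiles within Mfsd12 (2.65% to 64.7%), Bop1 (8.45% to 69.7%) and Ldlrad3 (8.19% to 68.4%) also rose.

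Gene lists fixed before the data were examined moved in different directions between the tissues. Ends of germline genes, which are normally methylated in somatic cells, averaged 43.0% ± 3.02 in placenta and 73.3% ± 1.96 in embryo (SD, n = 20), and 54 of 57 tested tiles were lower in placenta. They included the synaptonemal complex gene Sycp1 (29.3% against 84.9%), Slc25a31 (20.4% against 74.3%) and Stk31 (5.10% against 58.1%). Hox and other developmental regulators went the other way, with 165 of 191 tested tiles higher in placenta and 7 lower. Hoxb1 had 58.0% in placenta and 3.48% in embryo, the tile shared by Hoxa1 and Hoxa2 had 50.6% and 0.613%, and Sox14 had 52.2% and 3.36%. Of the blood list, 9 of 11 tested tiles were lower in placenta, among them the embryonic globin gene Hba-x (20.7% against 68.2%). Of the endothelium list, 12 of 22 were lower and 5 higher, with Pecam1 at 3.95% in placenta and 72.2% in embryo. Of the decidua list, 10 of 16 were higher in placenta and 0 lower, for example Vim (18.6% against 0.0497%) and Hoxa10 (20.4% against 0.381%).

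Trophoblast genes split, with 16 of 37 tested tiles lower in placenta and 6 higher. Krt7, a keratin of trophoblast, fell from 51.2% ± 4.35 in embryo to 6.68% ± 2.26 in placenta, and Gata3, a transcription factor of trophoblast, rose by 19.6 points. Protocadherins were lower in 21 of 56 tiles and higher in 5, as with Pcdhb12 at 23.4% in placenta and 72% in embryo. Growth and IGF genes were lower in 9 of 12 tiles and higher in 1, as with Igfbp2 (33.3% against 86.3%). The methylation machinery list was lower in 6 of 11 and higher in 0, and pluripotency genes were lower in 6 of 11 and higher in 4, with Zfp42 at 16.4% against 65.8%. Imprinted genes outside the germline regions were higher in 15 of 42 and lower in 15. With so many tiles past the threshold the tissue model separates nearly everything, so list counts describe direction and not rank against other genes. The placentas also hold maternal decidua and blood in unknown shares, which the labels do not describe.

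**Figure D2:**
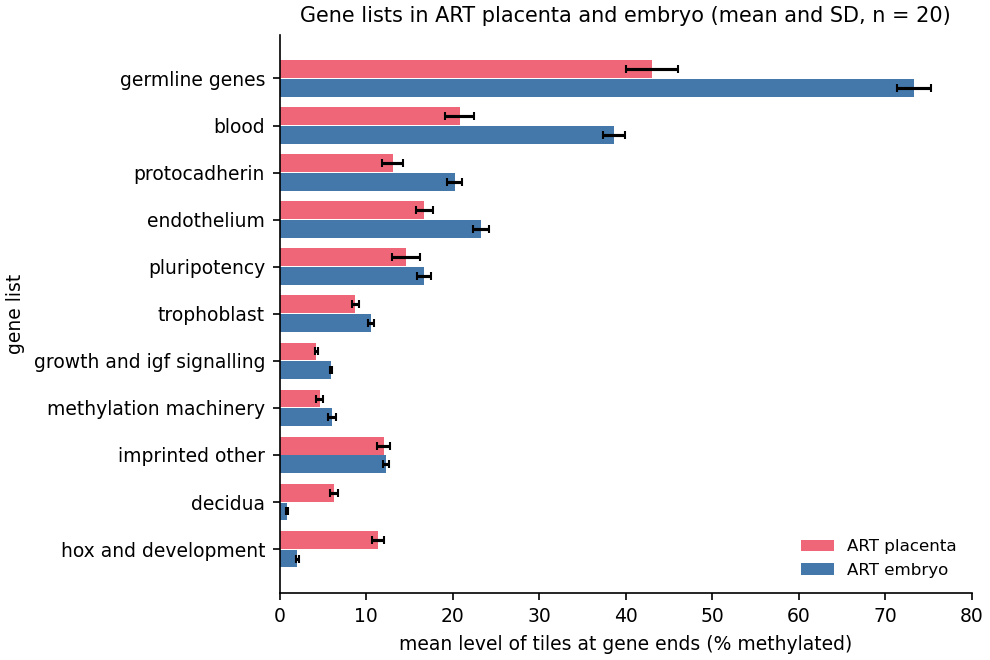
Bars give the mean methylation (%) of tiles at the ends of the genes in each list, in ART placenta and ART embryo, with error bars of 1 SD over 20 libraries each. Germline genes were at 43.0% in placenta and 73.3% in embryo, and Hox and developmental genes at 11.4% and 2.05%.

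The sex comparisons were carried by chromosome X. In ART embryos 1663 of 107902 tiles were lower and 46 higher in libraries labelled male, and 1677 of the 1709 called tiles lay on X. Tiles at Phf6 (6.63% ± 4.77 in male and 49.2% ± 9.70 in female, SD, n = 10), Mbnl3 (1.06% against 43.0%), Pdha1 (0% against 39.7%) and Pin4 (0% against 37.9%) were lower in male. The long noncoding RNA gene Firre was higher (96.1% ± 2.85 against 42.4% ± 10.8), as were Zfp36l3, Bcor and the autosomal Defb39. ART placentas gave 1137 called tiles of 131927, 1078 of them on X. Mbnl3 (2.65% against 34.8%), Atp11c (4.57% against 36.2%), Efnb1 and Mid2 were lower in male, and Fundc1, Bcor (80.5% against 51.1%), Firre and Ccdc22 higher. NAT placentas gave 923 called tiles of 104721, 888 on X, in the opposite direction. Atp11c was 34.3% ± 6.54 in placentas labelled male and 3.98% ± 2.64 in those labelled female. Usp27x, Tmem28 and Rpgr were also higher in those labelled male, and Bcor (57.5% against 85.9%), Diaph2, Foxo4 and Firre were lower.

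In ART embryos, a few tiles changed between Het and WT, and tiles at Efl1, Dysf and Ldlrad3 were called in both sexes. Over all 60 libraries the Efl1 difference lay mostly at a single CpG, as given below, so a sequence change there is not excluded. A tile within Efl1, a GTPase of ribosome maturation (chr7 82771301 to 82771400, 5 CpGs), fell to 47.9% ± 5.05 in female Het embryos from 69.4% ± 1.54 in female WT (SD, n = 5; adjusted p = 0.000521), and to 47.4% ± 2.68 from 67.1% ± 3.61 in male embryos (adjusted p = 0.00182). A tile beside Dysf, which encodes the membrane repair protein dysferlin (chr6 84005701), rose to 67.1% ± 17.8 from 26.1% ± 7.56 in female and to 61.6% ± 23.7 from 20.4% ± 4.22 in male embryos. A tile within Ldlrad3 (chr2 102009201) rose to 50.6% from 30.6% in female and to 53.9% ± 3.29 from 29.4% ± 2.35 in male embryos.

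Female Het embryos were also higher at Mmp1b, a collagenase family gene (63.4% ± 5.44 against 33.7% ± 7.41), at Cat, which encodes catalase (65.8% ± 3.26 against 43.9% ± 3.42), and at Begain, where Het values ran from 0 to 71.9% and WT values from 0 to 2.17%. They were lower at Pi4k2b (71.9% ± 1.39 against 85.8% ± 2.85). Male Het embryos were higher at Srgap3 (68.9% ± 10.9 against 22.6% ± 9.29, on 17 to 57 reads per library) and Mb21d2 (86.7% against 68.3%), and lower at Pin1rt1 (54.8% against 68.4%). In all, 10 of 116807 tiles passed in female embryos, 7 higher and 3 lower, and 12 of 110220 in male embryos, 8 higher and 4 lower. Of the tiles tested in both sexes, 4 were called in both in the same direction and 0 in opposite directions, where 0.000523 would be shared by independent lists. A limma model of log ratios called 1 tile in female and 0 in male embryos. The quasi-binomial fit without a filter on the mean level called 0 in both, and leaving out 1 library gave 4 to 18 and 5 to 24.

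In placentas the Efl1 tile was the one most often called between Het and WT. It was 34.7% ± 5.55 in male ART Het placentas and 58.0% ± 5.15 in male WT (SD, n = 5; adjusted p = 0.00736), the 1 tile called there of 157944. In NAT placentas labelled female it fell to 32.5% ± 3.52 from 62.2% ± 5.62 (adjusted p = 4.4e-05) and in those labelled male to 32.7% ± 3.82 from 62.8% ± 3.94 (adjusted p = 1.2e-05). The second called tile of the placentas labelled female lay on chr5 at 53398601 with no gene within 5 kb, and that of the placentas labelled male within Nipsnap3a (chr4 52989301), which rose to 23.4% ± 0.755 from 13.2% ± 1.41. These were 2 of 107764 and 2 of 127981 tiles. A limma model of log ratios and the quasi-binomial fit without a filter on the mean level each called 0 tiles in male ART placentas and in both NAT sets. Leaving out 1 library gave 0 tiles without WT 2, 3 or 4 and 7 without Het 2 in male ART placentas, 1 to 5 in NAT placentas labelled female (5 without WT 5) and 1 to 2 in those labelled male.

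Female ART placentas had 0 called tiles of 135897 in the quasi-binomial test, with 7879 at an unadjusted p under 0.05 and 0 called by limma. The smallest p values there belonged to Efl1 (36.4% ± 2.99 in Het and 58.1% ± 7.19 in WT), Ly75 (64.4% against 42.6%) and Lvrn (55.8% against 43.3%), with adjusted p = 0.172 for Efl1 and Ly75 and 0.202 for Lvrn. Tiles that stayed short of the threshold elsewhere were Ldlrad3 in male ART (36.1% against 16.7%, adjusted p = 0.0683) and labelled male NAT placentas (38.3% against 17.3%, adjusted p = 0.268), Filip1l in male ART (11.2% against 15.4%, adjusted p = 0.0683), and Hcn2 (29.5% against 57.8%, adjusted p = 0.112) and Dthd1 (70.3% against 86.0%, adjusted p = 0.261) in NAT placentas labelled female. In data simulated at the depth and spread of female ART placentas, 76% of tiles changed by 30 points and 4% of those changed by 10 points were called, so differences of 10 points were rarely detected at this depth and spread.

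A single genotype model over all 60 libraries, with the 6 sets of tissue, conception and sex label as strata, was chosen after the single comparisons had been seen. Of 93596 tiles, 160 passed adjustment and 39 differed by at least 10 points as well, 29 higher and 10 lower in Het. Of the 39, 38 had the same direction in all 6 sets, which is partly built in, since these sets chose the tiles. Sizes were uneven in some tiles. The Dysf tile at chr6 84005701 differed by 40.9 and 41.2 points in female and male ART embryos and by 0.607 in female ART placentas. Efl1 was 38.6% ± 7.59 in Het and 62.9% ± 6.16 in WT libraries (SD, n = 30; adjusted p = 3.78e-26). Its CpG at chr7 82771383 differed by −89.4 points. Its other CpGs differed by −9.19 points when averaged by CpG and by 1.03 points when their reads were pooled in each library (permutation p = 0.572). Ldlrad3 (41.3% against 21.2%), Mmp1b (45.7% against 22.2%), Ly75, an endocytic receptor of dendritic cells (66.2% against 48.9%), Cat (57.8% against 42.8%), Dysf, Olfr1318, Pde1a, Cspg5 and Rsad1 were higher in Het. Pi4k2b (59.3% against 72.4%) and Rif1 (31.3% against 45.9%) were lower. The tiles past adjustment lay close together in some places, with 13 on chr2 between 46296901 and 64749700, 12 on chr5 between 52580501 and 64800800, 10 on chr2 between 102009201 and 112160700, and 10 on chr9 between 4155901 and 8859900. Dnmt1 itself lies on chr9 at 20907206 to 20959888.

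**Figure D3:**
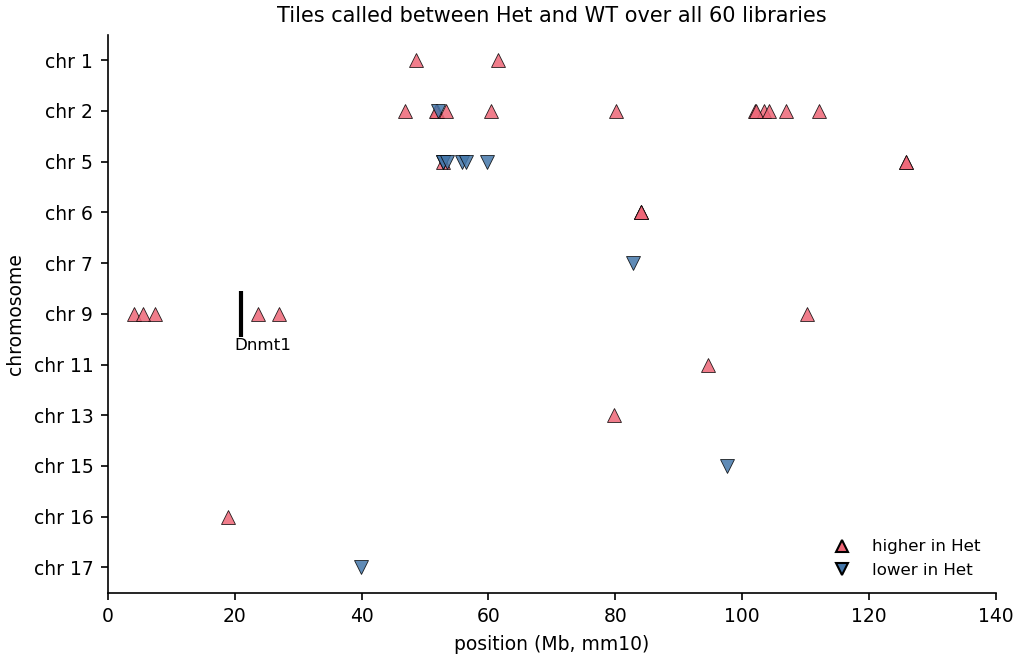
The horizontal axis is the position in Mb (mm10) and each line a chromosome; triangles are the 39 tiles called between Het and WT over all 60 libraries, pointing up where Het was higher (29 tiles) and down where it was lower (10 tiles). The bar marks Dnmt1, and 13 of the tiles lie on chromosome 2 and 9 on chromosome 5.

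Compared by label, ART and NAT placentas differed mostly on chromosome X, and the direction was opposite in the 2 labelled sexes. In WT placentas labelled female, ART placentas were higher at Atp11c, a phospholipid flippase (35.4% ± 6.77 against 4.93% ± 3.63, SD, n = 5), Mbnl3 (42.0% ± 17.6 against 0.548% ± 1.23), Mid2, Bhlhb9, Zic3 and Prrg3. They were lower at Bcor, a transcriptional corepressor (49.1% ± 5.50 against 84.6% ± 7.12), Firre, Foxo4, Shroom2, Chm and the chromosome 19 gene Csf2ra (43.1% against 71.1%). In WT placentas labelled male they were lower at Mbnl3 (3.19% ± 1.93 against 36.4% ± 16.3), Cask, Zic3, Gng12 (32.7% ± 12 against 64.7% ± 3.88), Bcl11b and Rbm15b. They were higher at Foxo4 (81.9% against 48.7%), Diaph2, Shroom2, Fundc1, Maged1 and the autosomal Dchs1 (35.1% ± 22.3 against 4.09% ± 4.4). Of 112754 and 131984 tiles, 917 (809 higher, 108 lower) and 1108 (104 higher, 1004 lower) were called in female and male WT placentas, of which 193 and 345 were autosomal.

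Het placentas gave the same picture. Those labelled female were higher in ART at Atp11c (37.0% ± 4.07 against 3.03% ± 0.527), Fhl1, Ppp1r3f, Tmem28, Efnb1 and Pcdh19 and lower at Bcor, Rab9, Firre, Tmem164, Nrip1 (31.8% against 64.3%) and Gpc1 (42.8% against 70.9%). Those labelled male were lower at another tile of Foxo4 (chrX 101254001, against chrX 101258301 in WT) and at Lonrf3, Mbnl3, Atp11c (4.55% against 38.1%), Lgals3, which encodes galectin (32.7% ± 19.5 against 74.4% ± 20.1), and the glycine transporter gene Slc6a5 (27.7% against 67.7%). They were higher at Maged1, Rhox3g, Fundc1, Fgd1, Gdpd5 (65% against 35.8%) and Ddr1 (37.6% against 9.36%). Of 110944 and 129754 tiles, 836 (668 higher, 168 lower) and 949 (85 higher, 864 lower) were called, of which 119 and 152 were autosomal. WT and Het shared 520 calls in placentas labelled female and 540 in those labelled male, all in the same direction, where independent lists would share 4.70 and 6.52. Female and male lists shared 466 tiles in opposite and 8 in the same direction in WT, and 481 and 8 in Het. Since NAT sex labels went against the sex chromosome reads, these 4 comparisons set placentas of unlike sex chromosome reads against each other.

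At the ends of listed genes, as labelled, ART placentas were lower at the endothelial gene Nos3 in Het placentas labelled female (by −19.9 points) and male (−14.1 points) and higher at the meiotic gene Hormad2 in placentas labelled female (by 13.4 points in Het, and called in WT as well). A tile shared by members of the gamma protocadherin cluster (chr18 37842501) differed by −17.8 points in Het placentas labelled female. A tile of the Hoxa cluster assigned to Hoxa3 (chr6 52200301) differed by −14.6 points in Het placentas labelled male. The pluripotency gene Tdgf1 differed by 14.2 points in WT placentas labelled female. Sox3 on X was higher in placentas labelled female and lower in those labelled male. None of these tiles was called when each ART group was set against the NAT group of the opposite label, but Nos3 and the protocadherin tile differed by similar amounts there. By the quasi-binomial test Nos3 differed by −20.9 points in Het labelled female (adjusted p = 0.125) and −13.1 points in Het labelled male (adjusted p = 0.599). The protocadherin tile differed by −21.2 points (adjusted p = 0.44), the Hoxa3 tile by −8.54 points and Tdgf1 by 9.26 points. Hormad2 differed by 3.31 points in Het and 6.93 points in WT, and the Sox3 tiles that could be tested by −4.17 to 5.52 points. In a model of conception over all 40 placentas, added after the data were seen, Nos3 (−14.0 points, adjusted p = 0.000135) and the protocadherin tile (−13.4 points, adjusted p = 0.000393) were called by the quasi-binomial test.

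**Figure D4:**
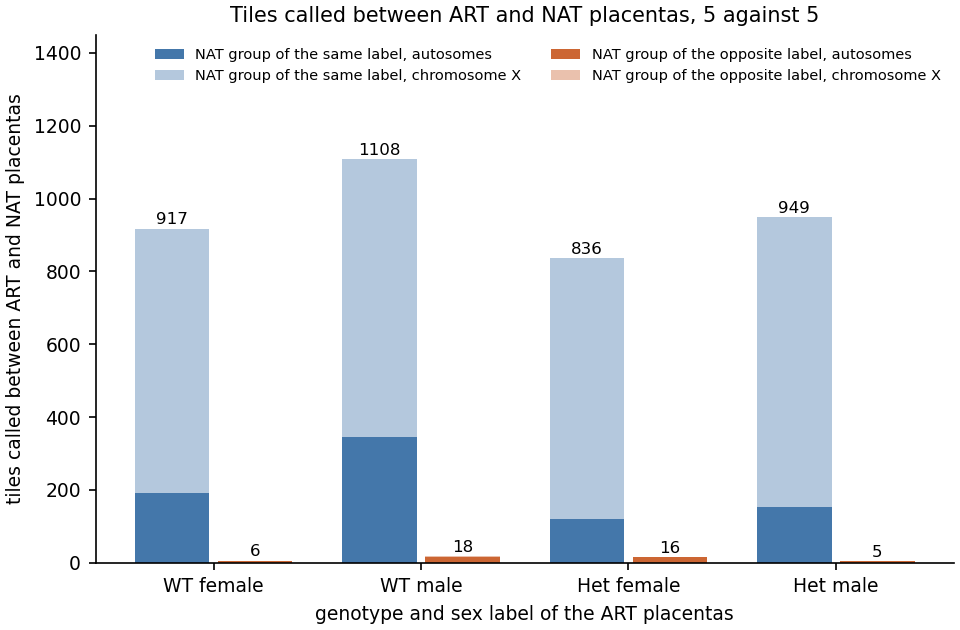
Bars count the tiles called between 5 ART and 5 NAT placentas, for each genotype and sex label of the ART placentas on the horizontal axis; solid parts are autosomal and pale parts on X. With the NAT group of the same label 836 to 1108 tiles were called, and with that of the opposite label 5 to 18.

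Setting each ART group against the NAT group of the opposite label, a comparison added after the sex chromosome reads were seen, left few differences, nearly all autosomal. A tile within Kifap3, a kinesin-associated protein gene (chr1 163812701), was higher in ART placentas: 83.9% ± 2.59 against 64.9% ± 4.27 in WT labelled female and 77.1% ± 4.2 against 56.5% ± 2.47 in Het labelled male (SD, n = 5; adjusted p = 0.0318 and 0.0131). A tile within Bmp4, a growth factor gene (chr14 46385901, 855 to 3918 reads per library), was lower in the same groups (14.5% ± 2.20 against 25.4% ± 3.04, and 13.3% ± 3.40 against 25.5% ± 2.75). WT placentas labelled male were lower at Clybl (14.5% ± 3.07 against 33.1% ± 4.88, adjusted p = 5.41e-05), Gng12, the integrin gene Itga6 (68.6% against 87.5%), Zfp444, Arhgef18 and Dnah9. WT placentas labelled female were lower at the homeobox gene Meis1 (20.5% against 34.6%). Het placentas labelled female were higher at Cog6 (71.7% against 40.5%) and lower at Glis1 (21.1% ± 5.91 against 57.1% ± 10.1), Dlgap1, Rpl13a, Grap, the incretin receptor gene Glp1r (50.4% against 62.3%) and Spag16. Het placentas labelled male were lower at Abhd8. In all, 6 of 131690 tiles were called for WT labelled female, 18 of 113239 for WT labelled male, 16 of 129460 for Het labelled female and 5 of 111239 for Het labelled male, with 9500, 8661, 10006 and 6906 at an unadjusted p under 0.05.

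The model of conception over all 40 placentas, with strata of genotype and opposite NAT label, called 492 of 97163 tiles, 167 higher and 325 lower in ART. Of these, 483 had the same direction in all 4 sets, which is partly built in, since the same sets chose the tiles. Kifap3 (78.3% ± 6.35 against 60.4% ± 7.12, SD, n = 20), the opioid-related receptor gene Oprl1 (64.5% against 37.5%), Ccdc114, Tcra (49.0% against 26.2%), Ddr1, a collagen receptor gene (32.7% against 11.3%), Cacna2d2 and Grid2 were higher in ART. Lrp2 (53.4% against 74.4%), Gng12, Phlpp1, Bach2, the nerve growth factor gene Ngf and a tile within Clybl (chr14 122229201) were lower. These genes were chosen from the called tiles after their values were seen. These are placentas from separate procedures, so conception cannot be parted from other handling that differed between the sets, and 295 tiles were called when 30 reads were required.

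Of the imprinted germline regions, which carry methylation set in the oocyte, Impact, Plagl1 and Kcnq1ot1 were lower in ART than in NAT placentas. Over 20 against 20 placentas, a test added after the data were seen, Impact had 27.6% ± 7.01 in ART and 35.6% ± 4.6 in NAT (adjusted permutation p = 0.00357). Plagl1 had 34.2% ± 5.08 and 41.5% ± 7.60 (adjusted permutation p = 0.00833). The Kcnq1ot1 region, whose methylation silences a long noncoding RNA on the maternal copy (chr7 143295401 to 143295700), had 21.7% ± 14.2 and 32.7% ± 5.95 (adjusted permutation p = 0.0241). At Kcnq1ot1 the ART placentas ran from 2.5% to 46.0%. Of the 20, 12 lay below and 2 above every NAT placenta, whose range was 21.9% to 43.3%. ART embryos had 38.6% ± 7.62. The spread at Kcnq1ot1 was itself larger in ART (adjusted permutation p = 0.00034). At Impact 12 of 20 ART placentas also lay below every NAT placenta, and its spread did not pass (adjusted permutation p = 0.294).

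The other regions did not pass the 20 against 20 test of means. Mcts2 had 40.3% in NAT placentas and differed by −0.307 points in ART. ART and NAT placentas had 53.6% and 53.7% at Nnat, 40.9% and 43.2% at Nespas, 44.3% and 46.2% at Peg10, 37.9% and 39.1% at Mest, 55.3% and 57.3% at Nap1l5, 31.7% and 33.0% at Snrpn, 40.5% and 34.8% at Inpp5f, 35.4% and 38.9% at Grb10, 39.9% and 43.1% at Zrsr1, 36.7% and 35% at Peg13, 29.2% and 33.8% at Slc38a4 and 38.5% and 42.3% at Airn. Peg3 was covered by 1 tile with as few as 2 reads and is not read here. In the planned tests of 5 against 5, adjusted over the list alone, only Impact in Het placentas labelled female passed (22.1% ± 5.23 in ART and 35.7% ± 2.80 in NAT, adjusted p = 0.00384), by the quasi-binomial test. The exact permutation test called 0 regions, but with 5 against 5 a single region cannot pass it, since the lowest exact p, 0.00794, adjusts to 0.127 over 16 regions. Between Het and WT no region passed in any of the 6 sets, where the quasi-binomial test gave an unadjusted p under 0.05 for 2 regions in female and 1 in male ART placentas and 0 elsewhere, and the exact permutation test for 2, 0 and 0.

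**Figure D5:**
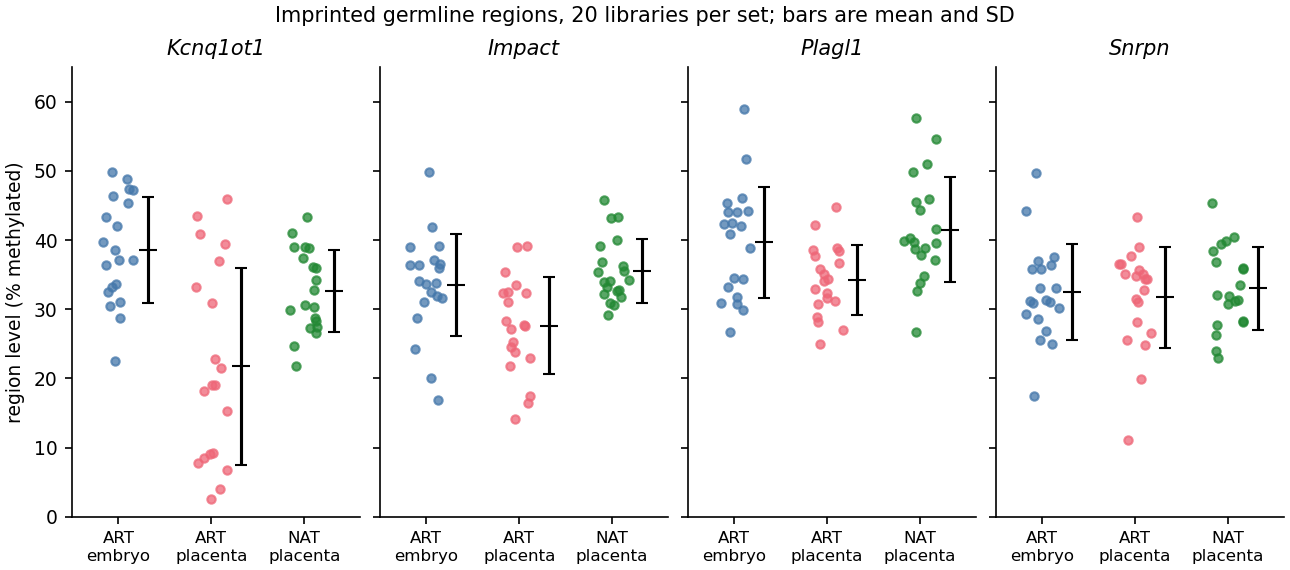
Points are libraries, 20 per set, and the vertical axis is the region's methylation (%); bars give mean and SD. Kcnq1ot1 in ART placentas spreads from 2.5% to 46.0% around a mean of 21.7%, while Snrpn has means of 32.5%, 31.7% and 33.0% in ART embryo, ART placenta and NAT placenta.

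No difference in the mean autosomal level or the variability of placentas and embryos passed its test in the 10 comparisons of 5 against 5, where at least 2 would have to reach the lowest exact p for any at that p to pass adjustment. Mean levels differed by −1.17 to 0.659 points, with exact two-sided permutation p between 0.0794 and 0.857 and a lowest adjusted p of 0.714. With all reads of a library pooled, 6 of the 10 differences turned direction, and ART minus NAT in Het placentas labelled female was 2.81 points (exact p = 0.0397, not adjusted). Variability, the percent of 123976 tiles in which a library lay at least 20 points from the median of the others in its group, had exact permutation p between 0.0714 and 0.810 and a lowest adjusted p of 0.536. The lowest p belonged to female ART embryos, with 0.177% ± 0.0290 in Het and 0.323% ± 0.188 in WT (SD, n = 5; exact p = 0.0714).

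Whether Het and WT differed more in 1 sex or conception was asked with 5 interaction models, and whether ART and NAT differed more in 1 labelled sex with 2. The quasi-binomial test called 0 tiles for genotype by sex in ART embryos, ART placentas and NAT placentas (5967, 6537 and 4711 at an unadjusted p under 0.05; limma called 1, 0 and 0) and 0 for genotype by conception in placentas labelled female and male (5593 and 5001; limma called 0 and 0). Conception by sex label gave 1418 tiles in WT and 1277 in Het placentas, of which 1196 and 1200 lay on X. Mbnl3, Mid2, Bcor and Diaph2 led in WT and Atp11c, Firre, Cnksr2 and Efnb1 in Het; Atp11c had 4.55% and 38.1% in ART and NAT Het placentas labelled male and 37.0% and 3.03% in those labelled female. Against the opposite NAT label both counts were 0, with 5473 and 4399 at an unadjusted p under 0.05.

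Over the 10 two-group comparisons, the mean level at gene ends of 11 lists gave 110 tests, and none passed adjustment (lowest adjusted p = 0.249, two-sided exact permutation tests). At this size at least 18 tests would have to reach the lowest exact p for any at that p to pass, so the outcome says little. The smallest exact p, 0.00794, is the lowest that 5 against 5 allows and fell on pluripotency genes in NAT placentas labelled female (10.3% in Het and 8.76% in WT), Hox and developmental genes in WT placentas labelled male (11.1% in ART and 12.2% in NAT) and the methylation machinery list in Het placentas labelled male (3.21% in ART and 3.98% in NAT). Against the opposite NAT label this last list had 1.81% in ART and 1.79% in NAT (exact p = 0.881), on partly other tiles, since 15 reads were required in other libraries. Over the 83 tiles that met this in all 3 groups, ART had 1.73%, the NAT group of the same label 2.18% (exact p = 0.00794) and that of the opposite label 1.79% (exact p = 0.675). The Hox and developmental list in WT placentas labelled male had 10.8% in ART and 11.8% in NAT of the opposite label (exact p = 0.0476, adjusted p = 0.399). Markers of decidua, the maternal part of the placenta, had lower means in ART in all 4 comparisons with the same and with the opposite label, and none passed adjustment. Both sets of comparisons hold the same placentas. Against the opposite label this was not particular to decidua, since the endothelium list and the Hox and developmental list were also lower in all 4. The mean over all tested tiles differed there by −0.179 and −0.622 points in WT labelled female and male and by −1.46 and −0.803 points in Het. Against the opposite label they had 5.89% in ART in WT labelled male, a difference of −1.10 points from NAT (exact p = 0.0159, adjusted p = 0.349), and 5.49% in ART and 6.06% in NAT in Het labelled male (exact p = 0.0397, adjusted p = 0.399). With the same label they had 5.61% and 6.16% in Het labelled female (exact p = 0.0159, adjusted p = 0.249, and exact p = 0.119 over the tiles shared by both labels). The endothelium list had 14.9% and 16.9% in Het labelled female against the opposite label (exact p = 0.0159, adjusted p = 0.349, and exact p = 0.0397 over the shared tiles).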

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

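Of the tests in this part, the share of single CpGs and the relation of Kcnq1ot1 to the mean autosomal level were written before their results were seen; the others, random splits included, were chosen after the results they bear on.

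Y reads in NAT placentas labelled female averaged 1606 RPM of autosomal reads, in the place of ART placentas labelled male. Depth does not account for it, since 7 of 10 NAT placentas labelled female lay within the depth range of those labelled male while every Y share was higher. An exchange of the female and male labels within the NAT set may explain it: 20 of 20 NAT placentas lay nearer the mean of the opposite ART label on Y reads, X reads and low X tiles, a criterion set after the values were seen. A stricter criterion written first, lying in the opposite ART range on both Y reads and low X tiles, was met by 10 of 20. It was met by only 14 of 20 ART placentas against others of their own label, so it decides little. In the ART range of their own label, on either of these measures, lay 0 of 20 NAT placentas. This argues against the sex labels as given for these 20. The wording of that prediction was changed once to suit the result and then put back, and whether the exchange happened in the labels or the samples stays open.

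The 39 tiles called between Het and WT over all 60 libraries lay near each other more often than random tiles. Of these, 38 had the same direction in all 6 sets, the sets that chose them. Of the 39, 17 had another called tile 1 kb to 2 Mb away, against a median of 4 and a highest of 12 in 1000 draws. A chromosome segment or strain variant carried along with the allele could give such grouping. Of 160 tiles past adjustment 12 lay within 20 Mb of Dnmt1 on chr9 (7.5%, against 1.19% of tested tiles), and of the 39 called tiles 5 did. However, 13 called tiles lay on chr2 and 9 on chr5, and a segment linked to Dnmt1 cannot account for these. Strain variants elsewhere in the genome were not tested. A sequence change at a single CpG would remove most of a tile's difference with that CpG, which was so in 6 of the 20 tiles that had 3 or more CpGs with at least 15 pooled reads in Het and in WT in each set (exact 95% interval 11.9 to 54.3%). It would also leave the other CpGs of a tile alike, but these differed in 16 of all 20, 2 of the 6 included (56.3 to 94.3%, highest adjusted permutation p = 0.0345). This argues against it as the whole difference in these 16 tiles. It stays open in the other 4 and in tiles not examined. Efl1 is among the 4, and its values are those such a change would give. Its CpG of largest difference differed by −89.4 points. The others differed by −9.19 points averaged by CpG and by 1.03 points with reads pooled (permutation p = 0.572). A change of sequence and a change of methylation at that CpG were not told apart. Less maintenance of methylation in Het would lower these tiles, and 10 of 39 were lower (25.6%, interval 13.0 to 42.1). The 29 tiles that were higher argue against it as the whole cause. The intervals given here take tiles as independent, which neighbouring tiles are not, so they are too narrow and decide nothing by themselves. An effect of the genotype on methylation at these tiles stays open and was not tested apart from the segments.

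Kcnq1ot1 was low in part of the ART placentas. Of the 20, 9 had a Wilson interval wholly below the lowest NAT placenta. These intervals count a read at each of the region's 17 CpGs that it covers, and they take the lowest NAT value as exact. They are therefore too narrow to exclude counting error. Within the 20 ART placentas the level had no relation to the mean autosomal level (r = −0.0883, permutation p = 0.709). Spearman's rho was 0.00451 (permutation p = 0.987), and r was 0.0228 without the 2 farthest. A loss shared by all ART placentas would not show in this relation and was not tested. In the conception model the mean over 97163 tiles differed by −0.736 points, ART minus NAT. Chance among 40 placentas gave an adjusted permutation p of 0.0241 for the means. An effect of ART could give this pattern, but the design cannot part it from any other difference between the procedures, which stays untested.

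Single libraries stood apart from the others of their group in 13 cases, over 12 groups and 21 measures, and chance alone sets apart about 1 in 20. The share of deviating tiles was 1.78% in male NAT WT placenta 2 (others 0.494 to 0.856). Female ART Het embryo 4 had 4060 Y positions (highest of the others 1199) and 24.3 X reads per 1000 autosomal reads (others 28.0 to 28.5). Male NAT Het placenta 5 had 897 RPM of Y reads (others 556 to 648), and female NAT WT placenta 5 had 15.4 X reads per 1000 autosomal reads (others 17.2 to 17.6). Mcts2 was 32.9% in female ART Het embryo 5 (others 39.3 to 41.4), 27.3% in female ART WT embryo 4 (others 40.2 to 44.2) and 30.1% in female NAT Het placenta 1 (others 41.2 to 44.4). Nap1l5 was 28.5% in female ART Het embryo 1 (others 40.1 to 44.7), Kcnq1ot1 28.8% in male ART Het embryo 2 (others 45.4 to 49.8) and Grb10 21.6% in male ART Het embryo 1 (others 35.8 to 37.8). Impact was 45.9% in male NAT Het placenta 3 (others 31.7 to 35.4) and 24.6% in male ART Het placenta 5 (lowest of the others 31.1).

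The effect of conception differed between the labelled sexes at 1418 tiles in WT and 1277 in Het placentas, and against the NAT group of the opposite label at 0 and 0.

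Random regroupings of the same libraries show how often another grouping calls as many tiles. These shares were not adjusted over the comparisons, and 100 or 25 splits can reach no lower than 1 in 100 or 1 in 25. Of 100 splits, 4 gave as many Het minus WT tiles as the 10 of female ART embryos (highest other 126) and 3 as many as the 12 of male ART embryos (highest other 94). Some splits thus called several times the real count, for a reason that was not tested, and chance is not excluded for these counts. Nor was chance excluded for the counts in male ART and in NAT placentas, with 9 splits for the 1 tile of male ART (highest other 6), 7 for the 2 of NAT labelled female (10) and 5 for the 2 of NAT labelled male (29). This is about the counts and not about each tile: Efl1, which is in all 3 of these lists, was lower in Het in all 6 sets, by −30.1 to −19.7 points. The model over all 60 libraries, these included, called 1 of 1, 2 of 2 and 1 of 2 of these tiles. Female ART placentas had 0 tiles, which every split reaches by construction (100 of 100; highest other 2), so the splits test nothing there. ART minus NAT gave 917, 1108, 836 and 949 tiles, reached by 1 of 100 splits each, the real one, with 22, 57, 12 and 20 as the highest others. Against the opposite label the 6, 18, 16 and 5 tiles were reached by 3, 1, 2 and 3 splits, with 8, 5, 27 and 6 as the highest others.

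Larger designs had 25 splits each. The real one alone reached its count for sex (1709, 1137 and 923; highest others 3, 0 and 1), tissue (97514; 40409), conception by sex (1418 and 1277; 315 and 52), the genotype model over 60 libraries (39; 1) and the conception model over 40 placentas (492; 0). Genotype by sex and genotype by conception had 0 tiles in each model, which all 25 splits reach by construction, so the splits test nothing there. The highest other counts were 1, 973 and 724, and 697 and 7. The regroupings of the interaction models mixed all libraries of a model, so effects of sex, genotype and conception were not kept apart from the interaction. What drove the larger counts was not tested.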

How the results depend on the processing

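Comparisons with the opposite NAT label, counts of autosomes alone, gene lists over the tiles shared by both NAT labels (none passed, lowest adjusted p = 0.2), the joint models and the fits without female ART Het embryo 4 were chosen after the data were seen; the other alternatives were planned. Leaving out single libraries aside, 113 results kept their direction and side of the threshold or stayed within 1.5 times, 57 moved and 10 reversed; the cause was not tested unless given. Counts follow the order Het minus WT in female and male ART embryos, female and male ART placentas and NAT placentas labelled female and male, then ART minus NAT in WT female, WT male, Het female and Het male.

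The plain binomial model, which leaves out the spread between libraries by construction, called 1279, 1616, 5806, 4270, 3708, 4336, 8172, 11038, 6842 and 9238 tiles. Without a filter on the mean level 0 were called in both ART embryo sets, male ART placentas and both NAT sets, and 446, 350, 395 and 393 for ART minus NAT. Limma on log ratios called 1 in female and 0 in male ART embryos, male ART placentas and both NAT sets, and 1 for genotype by sex in ART embryos. At 20 points, a stricter setting by construction, 7 were left in male ART embryos, 1 in NAT labelled male, 168, 215, 148 and 187 for ART minus NAT and 604, 125 and 112 for sex. Tiles of 500 bp gave 7 in male ART embryos, 3 in male ART placentas, 1 in NAT labelled male and 489, 614, 436 and 505 for ART minus NAT. On autosomes alone ART minus NAT had 193, 345, 119 and 152 tiles. Against the opposite label it had 6, 18, 16 and 5, X included, with 0 and 0 for conception by sex. Imprinted regions called were 4 with all tiles of the windows and 0 by exact permutation, which 5 against 5 cannot pass by construction unless 3 or more regions reach the lowest p. The joint genotype model called 27 tiles at 30 reads and 7 at 20 points, and the conception model 295 and 14, or 479 with labels as given.

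Replicate numbers were not treated as pairs (best match with the own number in 0 to 3 of 5); with a replicate block NAT labelled female had 1 tile, and other counts stayed within 1.5 times.

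Mean levels reversed when all reads were pooled, in female ART embryos (0.179 points), female ART placentas (1.62), NAT labelled female (−0.0794), and ART minus NAT in WT male (1.71), Het female (2.81, exact p = 0.0397) and Het male (1.15). Variability reversed with a deviation of 30 points in male ART embryos (0.000968) and NAT labelled male (−0.000484). Against the opposite label the WT female differences reversed for mean level (−0.136) and variability (0.0711).

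Leaving out 1 library gave 4 to 18 tiles in female ART embryos (6 without Het 1, 18 without Het 3, 4 without WT 3), 5 to 24 in male ART embryos (7 without Het 3, 6 without WT 2, 24 without WT 3, 5 without WT 4), 0 to 7 in male ART placentas (7 without Het 2, 0 without WT 2, 3 or 4), 1 to 5 in NAT labelled female (1 without Het 1, 2, 3 or 4 or WT 4, 5 without WT 5) and 1 to 2 in NAT labelled male (1 without Het 3 or WT 2). Female ART placentas stayed at 0, and ART minus NAT had 719 to 889, 848 to 1217, 725 to 883 and 821 to 1067. Without female ART Het embryo 4, sex in ART embryos had 1676 tiles and tissue 97772. Mean level differences ran from −0.313 to −0.0895 and 0.151 to 0.444 in ART embryos, −1.07 to −0.421 and −0.254 to 0.536 in ART placentas, −0.234 to 0.658 and −0.193 to 0.396 in NAT, and 0.115 to 1.01, −1.47 to −0.921, −0.721 to 0.00831 and −1.53 to −0.742 for ART minus NAT. They passed an unadjusted 0.05 in female ART placentas without Het 4 (−1.07, exact p = 0.0238) and in WT male without ART WT 1 or NAT WT 2 (−1.47 each, exact p = 0.0317). Variability differences ran from −0.293 to −0.0812, −0.183 to 0.0963, −0.809 to 0.00165, −0.159 to 0.463, −1.54 to −0.0449 and −0.433 to 0.486, and from −1.57 to −0.136, −0.811 to −0.0680, −0.959 to −0.0261 and −0.713 to 0.0847. Of these, 20 passed an unadjusted 0.05 and 17 reversed, and a median over fewer libraries raises the values of the reduced group by construction.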

Other observations

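The tests on replicate numbers in this part were chosen after the levels of the regions and the correlations over tiles were seen, except the one between unlike groups, which was written before its result. Some imprinted regions stood at other levels in placenta than in embryo, values that were not tested. Nnat, a brain-expressed imprinted gene, had 34.1% ± 5.52 in ART embryos and 53.6% ± 5.20 in ART placentas (SD, n = 20), and 53.7% ± 6.27 in NAT placentas. Nap1l5 had 41.6% ± 14.3 and 55.3% ± 9.03, Inpp5f 32.7% ± 7.28 and 40.5% ± 10.1, and the amino acid transporter gene Slc38a4 38.3% ± 6.38 and 29.2% ± 8.64 in ART embryos and placentas.

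Genes of several lists also differed between the tissues. The imprinted transporter genes Slc22a3 and Slc22a2 fell to 46.8% and 57.2% in ART placenta from 86.5% and 90.2% in embryo, and Ndn to 34.2% from 66.8%, while Asb4 rose to 51.5% from 10.6% and Kcnq1 to 72.1% from 36.4%. The VEGF receptor gene Flt1 fell to 32.2% from 81.8%, Igfbp5 to 36.1% from 83.6% and Igf1r to 35.5% from 70.7%. The trophoblast envelope gene Syna fell to 56.3% from 83.4% and Ctsr to 47.6% from 78.6%.

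A hypothesis that an embryo and a placenta of the same replicate number come from 1 conceptus arose because Nap1l5 was 95.5% in male ART Het embryo 2 and 80.6% in male ART Het placenta 2, the highest of each set. Over 16 imprinted regions the deviations of same-numbered libraries gave a one-sided permutation p of 0.0554, a test that holds the values it arose from. Over these 16 regions, Nap1l5 included, all 5 same-numbered correlations of female Het libraries were negative (−0.336 to −0.127). Without Nap1l5 the permutation p was 0.21 over 15 regions. Over 71374 autosomal tiles of intermediate level, 18 of 20 same-numbered correlations were positive, those of female Het among them (0.00722 to 0.0321), with a mean of 0.0139, a highest value of 0.0432 and a one-sided permutation p of 0.00458. Handling shared by all libraries of a number would raise the correlations between unlike groups too, where 32 of 60 were positive (mean 0.00196, permutation p = 0.301), which decides neither way. The tiles are consistent with a weak tie between same-numbered libraries of a group and the regions leave it undecided; whether a number marks a conceptus, a litter or shared handling stays open.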
